A study of Mus musculus with 8 samples.

How the data were processed

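The data were 8 RNA-seq libraries of KPCY mouse pancreatic cancer cells, 4 of a line stably transduced with a lentiviral inhibitor of miR-27a-3p and 4 of a line with a scrambled sequence. Per the labels' protocols, transduced cells were selected with 2 µg/mL puromycin for 7 days, grown in high-glucose medium (4.5 g/L) with 10% serum, and RNA was taken 24 hours after seeding. RNA with an integrity number of 7 or more went into a stranded, poly(A)-selecting Illumina kit and was read as paired ends of 59 bases on an Illumina NextSeq machine, per the labels' protocols. Such libraries do not hold mature microRNAs.

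The authors deposited a table of raw read counts per gene symbol, with 24421 rows and 1 column per library. Per the submitters' processing notes, bcl2fastq 2.20, Bowtie, STAR, DESeq2 1.36.0 and R 4.2.1 were used and the genome build was mm10, with no roles given. The counting tool, its annotation and its strand setting are not given in the sources used here. Without the strand setting, reads of a gene and an antisense neighbour cannot be told apart, and reads of near-identical copies can be split between them or dropped. Of 77 genes examined for this, the named ones among them, 24 share exon bases with another annotated gene, 10 of them with a protein-coding gene. Only some of these overlaps are mentioned below, so a gene without such a remark can share exon bases too. Symbols were matched to RefSeq and GENCODE annotation of GRCm38 (mm10), 23204 by current and 1041 by older symbol, with 149 unmatched or ambiguous. A further 27 symbols had been turned into dates, as spreadsheet programs do, and 4 of these rows shared 2 symbols. They were kept as rows without a gene name of their own. Coordinates are 1-based GRCm38.

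Library totals were 19165513 to 23542275 counts, and 8403 genes had 0 counts in all libraries. The 10 most abundant genes took 4.02% to 4.31% of the counts. At these depths a count of 0 allows up to 3 counts, 0.127 to 0.157 CPM, and such limits cover counting error only. Replicates were compared by a chi-square test of their counts, which gave 1.72 to 5.20 per gene within groups, so no library was a repeat of another. The pairs with scrambled replicate 2 gave the highest values, 5.03 to 5.20.

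Counts as deposited were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group with minimum count 10 and total 15, TMM factors from 0.991 to 1.01, glmQLFit and glmQLFTest on group alone, Benjamini-Hochberg adjusted p under 0.05, no fold threshold), which tested 11797 genes. Levels are TMM-scaled CPM. Before the data were examined, 35 gene lists were fixed. The 28 with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and adjusted over the lists, with the estimated correlation and fry beside it. Members were counted as rising or falling at the all-gene adjusted p and as adjusted over the list alone.

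For miR-27 sites, the longest GENCODE 3′ UTR of each gene was searched for the 8mer ACTGTGAA. Per library, the mean log2 CPM of site genes minus that of genes without the core CTGTGA, matched in 5 strata of expression and 10 of UTR length, was compared between groups by an exact two-sided permutation test over 70 arrangements, whose smallest p is 0.0286. After the data were seen, runs of adjacent genes were searched with windows of 15 tested genes against 1000 shuffles of gene order, with the limit at the 95th percentile of the largest window medians. The run found was cut at the 2 steps that left the smallest absolute deviations from the segment medians, and segments with a median beyond the limit were kept as the block, so that its genes share a direction partly by this choice.

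The rule for named genes was fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, without predicted or clone names, where ties in adjusted p went to the larger change. It added up to 3 called members with the smallest adjusted p, in the list's direction, from each called list and the called member with the smallest adjusted p from every other list. Up to 4 called members came from the lists of miR-27 targets, cachexia factors, epithelial and mesenchymal genes. Whatever their values, the miR-27 locus and Trp53 were added. Some genes that the rule takes are not reported here.

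Alternatives fixed beforehand were DESeq2's size factors, upper-quartile normalization, no filter and a stricter filter (1 CPM in 4 libraries), the replicate number as a block, DESeq2 1.42.0, limma-voom, an adjusted p under 0.01, a test against a fold of 1.2, other list tests, other site and control definitions, and leaving out each library. The edgeR test, camera, the site test and the block search were tested on simulated counts of this comparison. Over 11729 genes, edgeR recovered 65.7% of genes changed 1.2-fold, 94% at 1.5-fold and 100% at 2-fold, with 5.98% false calls. Only a small share of the genes was changed, against 47.9% called in the data, so the share recovered in the data can differ. Camera called only the list that had been lowered. The site test returned 0.0221 for a shift of 0.02 put in and −0.00192 with none, and the block search found 1 block put in and 0 with none. Each gene's counts were drawn independently, and no other difference was put in between the groups. The simulations therefore do not show how camera and the site test behave with correlated genes or with other differences between the lines. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Small-RNA and DNA libraries were not analysed here, so neither the mature microRNA nor gene copy number was measured.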

Results

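Poly(A)-selected RNA was sequenced from KPCY cells, a mouse line of pancreatic cancer cells described in the labels as male. The comparison was between a stable line transduced with a lentiviral inhibitor of miR-27a-3p (the knockdown, 4 libraries) and a line transduced with a scrambled sequence (4 libraries), in a series on fibroadipogenic progenitors and cachexia in pancreatic cancer. It asks which transcripts of the cancer cells differ when miR-27a is inhibited. The deposited counts summed to 20802357, 20021056, 23542275 and 20799062 in scrambled replicates 1 to 4, and to 19373530, 19165513, 19404534 and 21735023 in knockdown replicates 1 to 4. Levels are mean CPM (counts scaled to library size) ± SD over n = 4 libraries, knockdown first, and fold changes are knockdown over scrambled from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p. The labels call the libraries biological replicates but name 1 stable line per group, so the p-values measure the spread between cultures or libraries of these lines and not between independent transductions.

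The targeted locus gave almost no reads in this assay, which does not capture mature microRNAs. The Mir27a precursor (GRCm38 chromosome 8, 84208672 to 84208758) had 1 count in knockdown replicate 2 and 0 in the other 7 libraries, and Mir27b, Mir23a and Mir24-2 had 0 in all 8. A count of 0 allows up to 3 counts per library, 0.127 to 0.157 CPM at these depths, for counting error only. The host gene of Mir27b, listed as 2010111I01Rik (Aopep, chromosome 13), had 15.8 ± 1.70 against 17.7 ± 0.842 CPM (log2 fold change −0.16, adjusted p = 0.0891), and its adjusted p was 0.0378 without knockdown replicate 4. Its exons overlap those of Mir27b and of Fancc on the opposite strand, so its counts are uncertain. The libraries therefore give no measurement of how far miR-27a itself was lowered. Trp53, the p53 tumour suppressor and a driver of this cancer, fell by 0.17 on the log2 scale, 257 ± 4.48 against 289 ± 5.83 CPM (adjusted p = 5.8e-06).

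Among genes with a mean of at least 5 CPM, the 6 largest rises were from low levels in the scrambled cells. Hs6st2, a heparan sulfate sulfotransferase (chromosome X, 51386637 to 51681705), rose 10.6-fold to 30.1 ± 0.702 from 2.83 ± 0.564 CPM (SE 0.0922 on the log2 scale, adjusted p = 9.45e-19). Dapk1, a death-associated protein kinase, rose 7.66-fold (19.5 ± 0.721 against 2.54 ± 0.641 CPM) and Ptprd, a receptor-type tyrosine phosphatase, 5.29-fold, from 2.02 ± 0.440 CPM. Cldn18, a tight-junction claudin of stomach and lung, rose 4.71-fold (13.1 ± 1.49 against 2.76 ± 0.369 CPM), Nbea, a vesicle-trafficking protein, 4.39-fold, and Mxd4, a MAX partner that opposes Myc, 4.03-fold (adjusted p at most 9.97e-11 for these genes). Nbea and Mxd4 share exon bases with genes on the opposite strand, and so does Ptprd at 7 bases.

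The 6 largest falls among genes of that level all lay near the start of chromosome 5. Tmem243 fell 10.7-fold (5.67 ± 0.695 against 60.7 ± 1.38 CPM), and Cyp51, the lanosterol demethylase of cholesterol synthesis (4080674 to 4104697), fell 8.05-fold (247 ± 7.01 against 1989 ± 179 CPM, log2 fold change −3.01, SE 0.0435, adjusted p = 1.54e-24). Abcb1b, a P-glycoprotein drug exporter, fell 7.56-fold (83.4 ± 3.22 against 630.5 ± 24.4 CPM). Cfap69, a cilium protein, fell 7.17-fold, Fzd1, a Wnt receptor, 6.96-fold and Dbf4, the activating subunit of the Cdc7 replication kinase, 6.78-fold (148 ± 0.730 against 1001 ± 10.8 CPM), with adjusted p at most 7.39e-18 for these falls. Tmem243 shares 404 exon bases with Dmtf1 and Cyp51 shares 166 with Akap9, each on the opposite strand. Abcb1b has a close relative in Abcb1a, which also lies near the start of chromosome 5 and fell 6.44-fold. The exact folds of Tmem243, Cyp51 and Abcb1b are therefore uncertain.

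**Figure D1:**
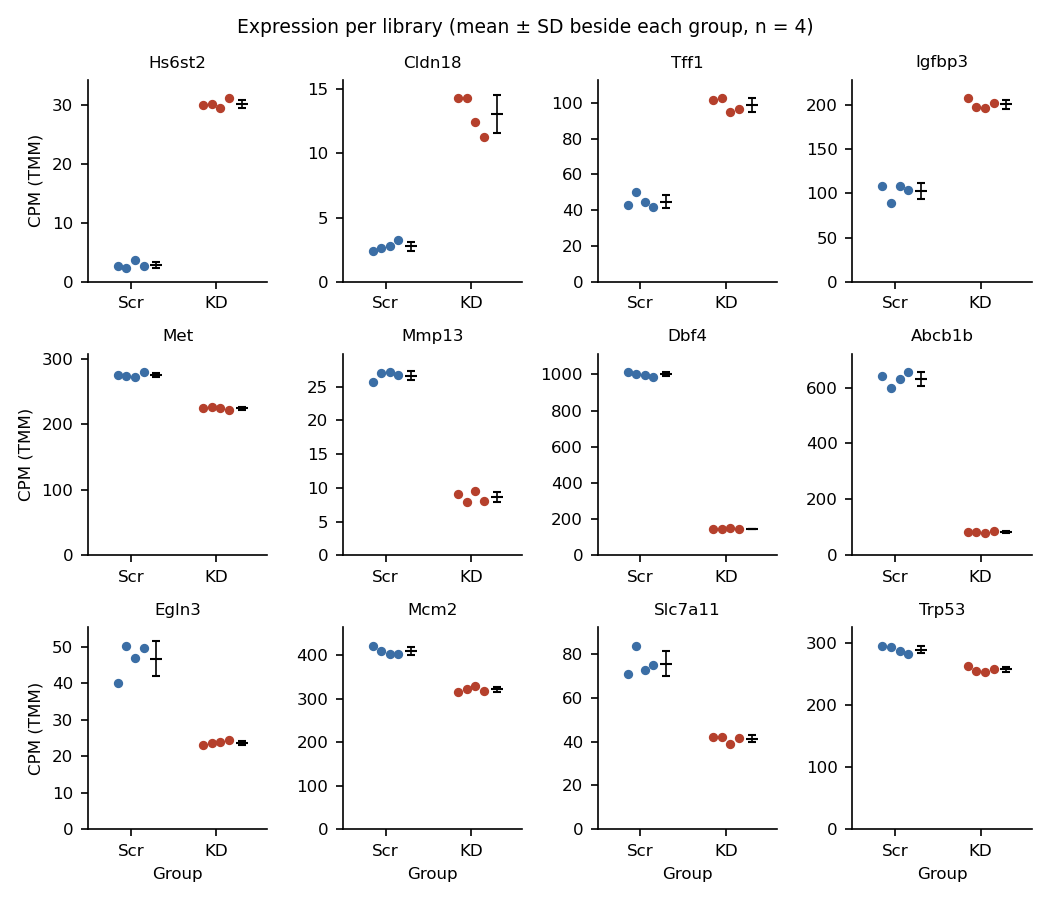
CPM (TMM-scaled, y axis from 0) of 12 named genes in the 4 scrambled (Scr) and 4 knockdown (KD) libraries. Points are libraries and bars show the mean ± SD. Hs6st2 was at 29.4 to 31.1 CPM in the knockdown libraries and at 2.37 to 3.64 in the scrambled ones.

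Across the transcriptome, 5645 of 11797 tested genes (47.9%) differed at adjusted p under 0.05, 2804 higher and 2841 lower in the knockdown line. Most differences were small. The median absolute log2 fold change of the called genes was 0.227, 57.8% of them were under 0.26, and 357 reached 1 (201 up, 156 down), or 569 when low genes were not filtered out. Replicates were close, with a median biological coefficient of variation of 0.0372. Scrambled replicate 2 was the scrambled library furthest from the others, with a chi-square per gene of 5.03 to 5.20 against each of them, where their own pairs gave 1.79 to 2.31. Without it 6004 genes were called, 3002 in each direction.

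The falls on chromosome 5 formed a block. The windows that showed it covered 46 genes, 39 called lower and 2 higher, and its end was then set where the fold changes stepped. All 37 tested genes from Cdk6 to Gnai1 (3341004 to 18360413), the first tested genes of the chromosome, fell. The first 30, from Cdk6 to Tmem243, had a median log2 fold change of −2.60 (6.05-fold lower) and the next 7, from Dmtf1 to Gnai1, −1.54 (2.91-fold lower). From Phtf2 at 20758664 onward the next 39 genes had a median of 0.14, with 2 lower and 20 higher. In a search with windows of 15 adjacent genes this was the 1 block whose absolute window medians exceeded the limit of 0.367 set by shuffled gene order. The largest absolute window median elsewhere was 0.365, on chromosome 6. The block supplies 37 of the 2841 falls and 37 of the 156 falls of at least 1 on the log2 scale.

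**Figure D2:**
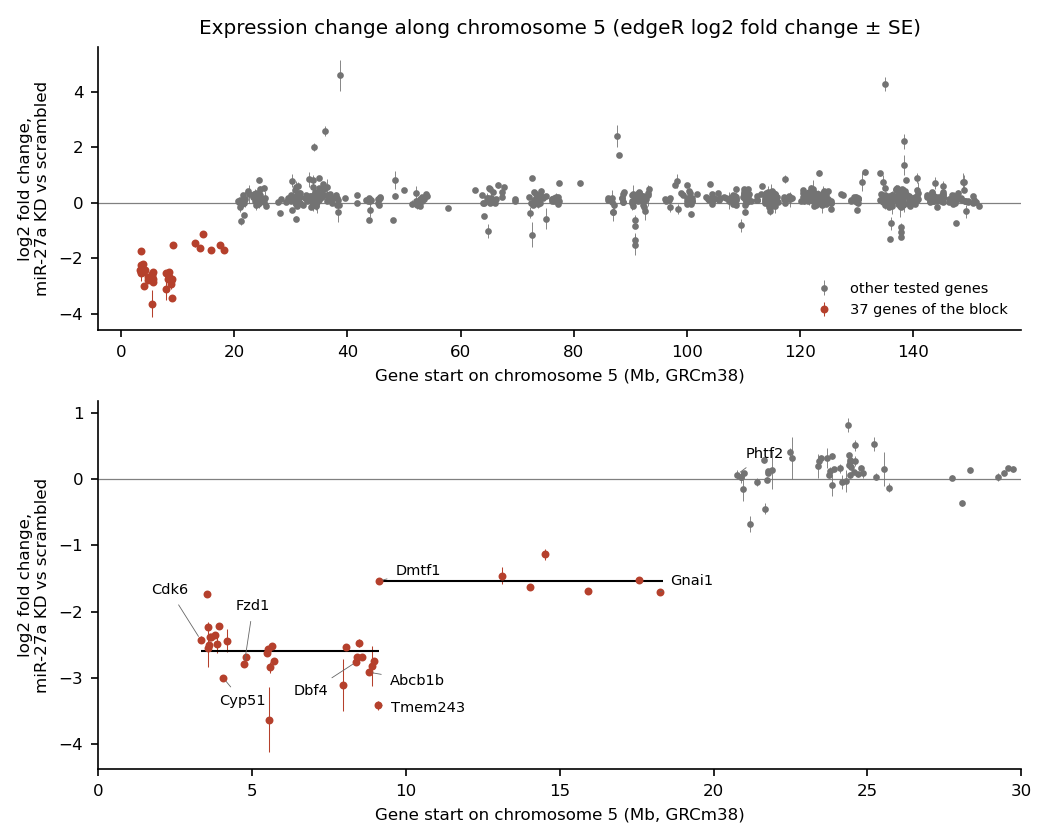
Log2 fold change (knockdown over scrambled, y axis) ± SE of tested genes against position in Mb (x axis) on chromosome 5, whole and over its first part. Red points are the 37 genes of the block and black lines in the lower panel are the medians of its segments, −2.60 and −1.54.

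The tested genes of whole chromosomes also differed as groups, by much smaller amounts. Chromosome 8, which carries Mir27a, had the largest median of the 21 chromosomes, a log2 fold change of 0.208 over 649 genes, with 407 called higher and 35 lower. Per library, the chromosome 8 median relative to the genome was 0.202 ± 0.00808 in the knockdown and −9.48e-05 ± 0.005 in the scrambled libraries (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0316 over the chromosomes). As 19 of the 21 chromosomes gave this smallest p, it does not single out chromosome 8. With the block left out, chromosome 5 had a median of 0.148, chromosome 19 0.105 and chromosome 12 0.096, while chromosome 9 had −0.0855 and chromosome 6 −0.108. For each of these 6 chromosomes the p over 10000 random gene sets was 1e-04, the smallest they can give (adjusted p = 0.00015 over the chromosomes). Chromosomes 1, 4, 7, 11, 14, 15, 16 and 18 gave the same p, so it does not set these 6 apart. A further reservation is that genes are not independent replicates.

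**Figure D3:**
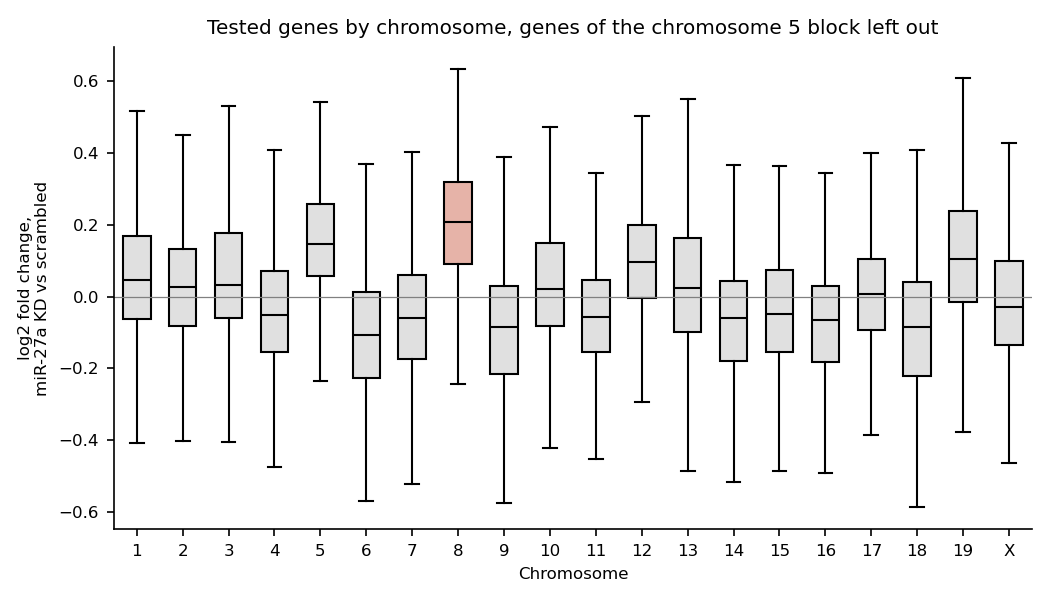
Log2 fold change (knockdown over scrambled, y axis) of tested genes by chromosome (x axis), block genes left out. Boxes span the quartiles with a line at the median, whiskers reach at most 1.5 times the box height, and points beyond them and the 4 tested Y-linked genes are not drawn. Chromosome 8, coloured, has a median of 0.208.

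Genes reported in the literature as miR-27 targets went both ways. Of 36 tested, 11 rose, 10 fell and 15 did neither (12 and 11 adjusted over the list alone), with a median log2 fold change of 0.00403. Lpl, lipoprotein lipase, rose 3.50-fold (11.5 ± 0.481 against 3.28 ± 0.689 CPM) and lies on chromosome 8. Mmp13, a collagenase, fell 3.08-fold (8.65 ± 0.783 against 26.6 ± 0.674 CPM) and Met, the receptor of hepatocyte growth factor, 1.23-fold. The list did not differ from other genes by camera (adjusted p = 0.972 over 28 lists). The fry test, which asks of the list alone whether its genes move on balance in 1 direction, called it (adjusted p = 0.00639). It called 18 of the 28 lists, so this call is not particular to miR-27 targets. With 11 rises and 10 falls it is not read as a rise of the targets, and camera's direction for the list was down.

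Genes with a perfect miR-27 8mer site (ACTGTGAA) in the 3′ UTR were very slightly higher in the knockdown. Relative to 5779 genes without the 6mer core, matched on expression and UTR length, the 730 site genes had a mean log2 CPM of −0.0236 ± 0.0043 in the knockdown and −0.0468 ± 0.00539 in the scrambled libraries (SD, n = 4). The difference of 0.0232, a 1.02-fold shift, had an exact two-sided permutation p of 0.0286, while camera, which sets the site genes against all others, gave p = 0.463. Among site genes 27.3% rose and 22.7% fell, against 22.5% and 25.6% of genes without the core, which were not matched for these shares. With only genes of at least 1 CPM in 4 libraries the shift was 0.01325 (exact p = 0.0571), and with 8mer or 7mer-m8 sites it was 0.01132 (exact p = 0.0286). Reordered versions of the 8mer gave shifts as large in either direction, from −0.107 to 0.0616 over the middle 95% of 200. They lay in 15 to 752 genes, almost all in fewer than 730, and small sets scatter more, so this range is not one of like-sized sets. Reordered 8mers in 752, 684, 623 and 561 genes gave −0.013, −0.0008, −0.0046 and −0.0145. Those in 550, 549 and 538 genes gave 0.029, 0.0021 and −0.025.

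Cell-cycle genes were lower in the knockdown. Of 53 tested, 39 fell, 4 rose and 10 did neither (the same counts adjusted over the list alone), with a median log2 fold change of −0.18. Cdk6, a G1 kinase inside the chromosome 5 block, fell 5.39-fold (37.8 ± 0.984 against 203 ± 19.1 CPM). Mcm2, a subunit of the replicative helicase, fell 1.27-fold (321 ± 6.18 against 409 ± 8.94 CPM) and Mybl2, a transcription factor of dividing cells, 1.42-fold. Camera with its preset correlation gave adjusted p = 1.26e-08, and 2.43e-08 without the block genes. The adjusted p was 0.109 with an estimated correlation, with which 0 of the 28 lists was called. Camera called 5 lists, and 3 of the other 34 splits of the libraries into 4 and 4 called as many or more. These 3 set scrambled replicate 2 with 3 knockdown libraries, so they keep 3 of the 4 libraries of each group together. Which lists they called is not given.

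Cholesterol-synthesis genes fell almost throughout. Of 25 tested, 22 fell, 1 rose and 2 did neither (the same adjusted over the list alone), with a median of −0.358. Beside Cyp51, which lies in the block, Sqle, squalene epoxidase, fell 1.23-fold (178 ± 2.66 against 219 ± 11.8 CPM) and was chosen after its values were seen. Camera gave adjusted p = 3.16e-08, and 1.46e-07 without the block genes, and adjusted p = 0.584 with an estimated correlation. In a test of scrambled replicate 2 alone against the other 3 scrambled libraries, which takes its spread from those 3, it was higher for 12 of the 25. Without it 22 still fell (adjusted p = 4.3e-08).

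Glycolysis and hypoxia genes and NRF2 and oxidative-stress genes were lower as well. In the first list 23 of 35 fell, 2 rose and 10 did neither (24 and 2 adjusted over the list alone), with a median of −0.24. Egln3, an oxygen-sensing prolyl hydroxylase, fell 1.97-fold (23.7 ± 0.594 against 46.8 ± 4.71 CPM), and the glycolytic enzymes Tpi1 and Pkm 1.28-fold and 1.18-fold. In the second, 24 of 37 fell, 3 rose and 10 did neither (27 and 4 adjusted over the list alone), with a median of −0.158. Slc7a11, the cystine importer, fell 1.83-fold (41.3 ± 1.54 against 75.6 ± 5.71 CPM), Gclc, which starts glutathione synthesis, 1.47-fold and Fth1, the ferritin heavy chain, 1.28-fold. Camera gave adjusted p = 8.62e-06 and 4.13e-05 for the lists in this order. With an estimated correlation the adjusted p values were 0.584 and 0.233. Tpi1, Pkm and Fth1 have near-identical pseudogene copies and are uncertain.

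Genes of the classical subtype of pancreatic cancer were the list called higher. Of 24 tested, 14 rose, 3 fell and 7 did neither (the same adjusted over the list alone), with a median of 0.219. Ctse, cathepsin E, rose 1.51-fold (720.1 ± 3.79 against 478.5 ± 12.6 CPM), Tff1, a trefoil peptide of gastric mucus, 2.21-fold (98.9 ± 3.77 against 44.8 ± 3.69 CPM) and Cldn18 4.71-fold. Camera gave adjusted p = 0.00539, and adjusted p = 0.325 with an estimated correlation. Of 12 basal and squamous subtype genes 7 rose, 4 fell and 1 did neither (adjusted p = 0.477), and Cav1, caveolin, fell 1.63-fold (264 ± 2.39 against 429 ± 14.5 CPM).

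**Figure D4:**
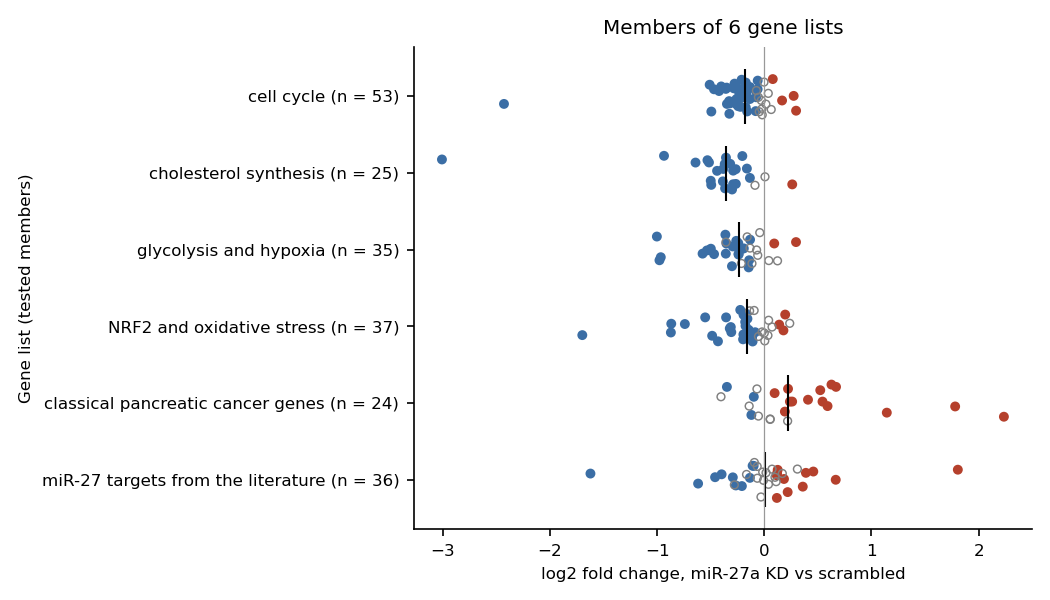
Log2 fold change (knockdown over scrambled) of the tested members of 6 gene lists. Filled red points rose, filled blue points fell and open points did not pass adjusted p under 0.05, with a black bar at each list's median, from −0.358 for cholesterol synthesis to 0.219 for the classical subtype.

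Neither the epithelial nor the mesenchymal list was called. Of 24 epithelial and junction genes 12 rose, 5 fell and 7 did neither (12 and 6 adjusted over the list alone, camera adjusted p = 0.139). Cldn4, a claudin, stood at 4.51 ± 0.246 against 0.231 ± 0.132 CPM, a fitted 19.5-fold rise with the scrambled libraries near the floor. The P-cadherin Cdh3, on chromosome 8, rose 2.45-fold (7.68 ± 0.488 against 3.13 ± 0.165 CPM), Muc1, a membrane mucin, 1.33-fold and Krt7, a ductal keratin, 1.24-fold (2536 ± 35.2 against 2039 ± 40.8 CPM). Of 18 mesenchymal genes 8 rose, 4 fell and 6 did neither (adjusted p = 0.331). Col5a1, a fibrillar collagen chain, rose 2.70-fold, Thbs1, thrombospondin, 1.75-fold and Fn1, fibronectin, 1.21-fold (474.5 ± 6.48 against 392 ± 15.6 CPM), while Tnc, tenascin, fell 3.81-fold (3.38 ± 0.611 against 12.9 ± 0.742 CPM). Extracellular matrix and basement membrane genes were split, with 12 rising, 10 falling and 9 doing neither of 31 (adjusted p = 0.801).

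Secreted factors linked to cachexia were not called as a list. Of 23 tested, 5 rose, 9 fell and 9 did neither (adjusted p = 0.477). Igfbp3, an IGF carrier, rose 1.96-fold (201 ± 5.16 against 102.5 ± 8.88 CPM). Fst, follistatin, which binds activins and myostatin, fell 2.24-fold (13.8 ± 1.59 against 31.0 ± 2.78 CPM), the neutrophil chemokine Cxcl5 1.81-fold and Tgfb1 1.28-fold. NF-kB and inflammatory genes had 4 rises and 9 falls of 19 (4 and 10 adjusted over the list alone, adjusted p = 0.427), and Ptgs2, the inducible cyclooxygenase, rose 1.75-fold. Of 15 interferon-response genes 4 rose and 3 fell (adjusted p = 0.627), and Irgm1, an interferon-induced GTPase, stood at 54.1 ± 1.81 against 38.6 ± 3.48 CPM (adjusted p = 1.02e-07). None of 11 MHC class I genes rose and 5 fell (adjusted p = 0.0957), among them H2-D1, 1.38-fold lower, whose counts are uncertain because the H2 genes are near-identical. Without scrambled replicate 2 the list's adjusted p was 0.0399 with the preset and 0.366 with an estimated correlation.

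Signalling lists held called genes in both directions. TGF-beta response genes had 7 rises and 8 falls of 24 (7 and 9 adjusted over the list alone, adjusted p = 0.627), with Pmepa1, a feedback inhibitor, up 1.41-fold. MAPK output genes had 10 rises and 8 falls of 27 (adjusted p = 0.982), with the ERK phosphatase Dusp6 up 1.25-fold. Immediate early genes had 11 rises and 5 falls of 23 (12 and 5 adjusted over the list alone, adjusted p = 0.45), with the transcription factor Maff down 1.79-fold. Wnt targets and regulators had 7 rises and 8 falls of 19 (adjusted p = 0.707), Fzd1 in the block among the falls. YAP and TEAD targets had 12 rises and 9 falls of 25 (adjusted p = 0.553), with F3, tissue factor, up 1.43-fold. p53 targets had 7 rises and 7 falls of 27 (adjusted p = 0.982), with Pmaip1, the BH3-only protein Noxa, down 1.37-fold. The driver list had 2 rises and 1 fall of 7 (2 and 2 adjusted over the list alone, adjusted p = 0.982).

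Metabolic and organelle lists other than those above were not called. Fatty acid and lipid storage genes had 12 rises and 19 falls of 46 (12 and 20 adjusted over the list alone, adjusted p = 0.477), with Acsl4, an acyl-CoA synthetase, down 1.38-fold. Nuclear-encoded respiratory chain genes had 4 rises and 11 falls of 43 (4 and 10 adjusted over the list alone, adjusted p = 0.609), with Uqcrc1 of complex III down 1.19-fold. Unfolded protein and ATF4 response genes had 8 rises and 16 falls of 40 (adjusted p = 0.235). Without scrambled replicate 2, 21 fell and the adjusted p was 0.036, and 0.444 with an estimated correlation. Autophagy and lysosome genes had 17 rises and 13 falls of 43 (18 and 13 adjusted over the list alone, adjusted p = 0.477), with Lamp1, a lysosomal membrane protein on chromosome 8, up 1.25-fold. Extracellular vesicle genes had 13 rises and 11 falls of 38 (13 and 12 adjusted over the list alone, adjusted p = 0.982), with annexin Anxa2 down 1.25-fold (2595 ± 28.8 against 3250 ± 39.0 CPM).

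The microRNA machinery had 4 rises and 4 falls of 20 (adjusted p = 0.982), with Zcchc11 (Tut4), a terminal uridylyltransferase, down 1.49-fold. Cytosolic ribosomal protein genes had 10 rises and 10 falls of 45 (adjusted p = 0.982), with Rplp0 up 1.15-fold, a gene with pseudogene copies. Of 3 genes tested from the list of replication-dependent histones, 2 rose and 1 fell. The most abundant of them, H1f0 (mean 277 CPM), is a linker histone that is not replication-dependent. Hist1h2bc rose 2.34-fold, uncertain because histone genes are near-identical and most lack poly(A) tails. Counts not given separately were the same adjusted over the list alone, as for 22 of the 34 lists with a tested member. Median, mean and camera direction differed in sign for 7 lists, none of them called: miR-27 targets, interferon, p53, MAPK, microRNA machinery, drivers and ribosomal proteins.

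Markers of other cell types were mostly too low to test. Of the 20 fibroblast and stromal markers 4 were tested, 1 rose and 1 fell, and the actin-severing protein Gsn, which epithelial cells also express, rose 2.21-fold (65.2 ± 2.30 against 29.6 ± 4.13 CPM). Of 18 leukocyte markers 2 were tested and Cd14 fell by 0.26 on the log2 scale (63.8 ± 4.28 against 76.6 ± 3.91 CPM). Of 12 endothelial markers 4 were tested and Flt1, a VEGF receptor, fell 1.66-fold, from 24.8 ± 0.869 CPM. Cela1 was the acinar and islet marker tested, at 2.36 ± 0.441 against 3.29 ± 0.675 CPM (log2 fold change −0.48, adjusted p = 0.0297). Its call was lost without scrambled replicate 1 (0.0828), scrambled replicate 2 (0.0729), knockdown replicate 2 (0.097) or knockdown replicate 4 (0.0922), and by DESeq2 (0.0617). Of 4 Y-linked genes tested none rose, and Ddx3y, an RNA helicase, fell by 0.26 on the log2 scale (77.5 ± 3.47 against 93.0 ± 6.66 CPM). Mitochondrially encoded genes had 0 rows in the table.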

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

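No test in this part was chosen after its result was seen. In 134 groups of 4 libraries (the level of each gene taken by the rule for named genes and each library total), the highest or lowest library was set against the other 3. In 5 groups its gap to the nearest library was larger, relative to the range, than Dixon's 95% limit, where chance gives about 1 in 20. Tmem243, a gene of the chromosome 5 block, was at 6.705 CPM in knockdown replicate 1 and at 5.26 to 5.426 in the other knockdown libraries. Slc7a11 was at 38.96 CPM in knockdown replicate 3 and at 41.81 to 42.15 in the others. Irgm1 was at 33.44 CPM in scrambled replicate 2 against 39.66 to 40.88, and Lamp1 at 379.5 CPM in the same library against 389.1 to 390.8. The total of knockdown replicate 4 was 21735023 counts, against 19165513 to 19404534 in the other knockdown libraries.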

How the results depend on the processing

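The alternatives without the block genes, without chromosome 8 and with chromosome medians removed were chosen after the data were seen. The number of genes changed stayed within 1.5 times of 5645 under every normalization, filter and tool run (5061 by DESeq2, 5637 by limma-voom, 5842 without a filter) and was 1107 (584 up, 523 down) when tested against a fold of 1.2, as follows from the many small changes. The balance of directions depended on the normalization, with 3188 up and 2478 down of 5666 by the upper quartile against 2804 and 2841 by TMM. Genes changed by at least 1 on the log2 scale numbered 569 without the filter, against 357, since low genes enter. Leaving out each library in turn gave 5116 to 6004 genes (2532 to 3002 up, 2575 to 3002 down), 5 to 7 lists and a site shift of 0.01756 to 0.02413. With an estimated correlation 0 lists were called by camera (3 at an unadjusted p under 0.05), with fry's directional test 18 and with fry's mixed test 28. The site shift was 0.01325 (exact p = 0.0571) under the stricter filter and 0.01132 (exact p = 0.0286) with 8mer or 7mer-m8 sites. The cause was not tested. Same-numbered libraries did not deviate together (correlations −0.035 to 0.0201, 1 library closest to its own number), so the numbers were not taken as pairs. With the number as a block 5533 genes were called, and sign flips over the 4 pairs left the site shift at 0.02323 (exact p = 0.125, the smallest possible). Without the block genes 5608 genes and 5 lists were called and the site shift was 0.0196. With chromosome medians removed 4837 genes were called, 3979 of them shared with the uncorrected calls, and the MHC class I list joined the called lists (adjusted p = 0.0395, and 0.407 with an estimated correlation). Among named genes 6 calls were lost, each of them that of Cela1 (adjusted p = 0.0569 with chromosome medians removed), and 1 was gained, that of 2010111I01Rik without knockdown replicate 4. No called result changed direction, and 9 uncalled results (1 gene, 8 lists) changed sign while uncalled. Depth limits the genes near the floor, such as Cldn4, and at 1.2-fold the simulation, in which few genes were changed, recovered 65.7% of changes.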

Other observations

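Of the tests in this part, the one on left-out libraries for the chromosome 5 block was chosen after the result was seen, as were the alternatives without the block genes or chromosome 8, and the genes of the next paragraph were picked after their values were seen. Searching for blocks and comparing chromosomes, also per library, were prompted by the data as well.

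Outside the chromosome 5 block, the largest fall among called genes with a mean of at least 5 CPM was in Brsk1, a kinase of neuronal polarity, 5.23-fold (2.52 ± 0.387 against 13.2 ± 1.17 CPM, SD, n = 4 per group). Mgst1, a microsomal glutathione transferase, fell 3.93-fold, Tnip3, an inhibitor of NF-kB signalling, 3.21-fold, Hr, a nuclear receptor corepressor, 3.16-fold (11.8 ± 0.581 against 37.1 ± 3.96 CPM) and Wipf1, an actin regulator, 3.04-fold (11.8 ± 1.26 against 36.1 ± 1.07 CPM). Ehf, an epithelial ETS factor, fell 2.54-fold (18.5 ± 0.741 against 46.8 ± 3.48 CPM), and Trib2, Ppp1r1b and Piezo2 fell 2.74-, 2.62- and 2.53-fold. Among rises, Csn3, a casein, rose 3.31-fold (50.6 ± 2.03 against 15.3 ± 1.18 CPM), Ddah1 3.02-fold and Slc8a1, a sodium-calcium exchanger, 2.81-fold. Mmp15, a membrane-type metalloproteinase, and Has3, a hyaluronan synthase, rose 3.58-fold and 3.23-fold, and both lie on chromosome 8. Adjusted p was at most 2.88e-09 for each of these genes. Brsk1 shares 1054 exon bases with Tmem150b and Has3 352 with Chtf8, on opposite strands. Ppp1r1b shares 460 and Slc8a1 296 with noncoding genes on the opposite strand.

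Scrambled replicate 2 differed from the other scrambled libraries in 570 genes, 265 higher and 305 lower. This test sets 1 library against 3 and takes the spread from the 3 alone, as if the lone library varied like them. The same test called at most 8 genes for a knockdown library against the other 3. For the other scrambled libraries it called 0, but there replicate 2 was among the 3 and widened the spread. The genes with the smallest adjusted p were Fat1 (log2 difference −0.41), Hspg2 (−0.51), Kmt2d (−0.58) and Dync1h1 (−0.37), all lower, and 12 of the 25 cholesterol-synthesis genes were higher. Over the longest 5% of transcripts (568 genes) its median difference from the other 3 was −0.0588, against −0.0343 to 0.0537 for the other 7 libraries within their groups. Its correlation with length across genes was −0.0957, against −0.104 to 0.119. Whether RNA quality or library preparation set it apart stays open.

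No other split of the libraries called as many genes as the real one, but the comparison was nearly bound to give this. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real split, called as many genes, and the highest of the others was 0 by edgeR (81 to 1038 genes at an unadjusted p under 0.05, against 6370). Every other split puts libraries of both lines on each side, so the difference between the lines enters its spread. The splits therefore cannot decide whether chance gave the number of genes called. They also cannot tell the knockdown from other differences between the lines. For the gene lists chance was not excluded, since 4 of the 35 splits called at least the real 5 and the highest other called 8. Of the 4 splits that set scrambled replicate 2 with 3 knockdown libraries, 3 called 6 to 8 lists and 1 called 3. These splits keep 3 of the 4 libraries of each group together. The 18 splits with 2 libraries of each group on both sides called 0 to 2 lists.

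The fall of 37 adjacent genes on chromosome 5 has as a candidate explanation, a hypothesis, a difference in DNA copy number of the interval between the lines. Direct release from miR-27 would raise its targets and so does not account for a fall. A single library is argued against, since all 37 were called lower whichever library was left out. The 32 genes of the interval too low to be tested had no part in finding the block. Of these, 14 had a count, with 28 counts in all in the knockdown and 146 in the scrambled libraries. Their summed level was 0.351 ± 0.0713 CPM in the knockdown against 1.72 ± 0.195 in the scrambled libraries (n = 4). This ratio of 0.204 (exact two-sided permutation p = 0.0286) is as a copy-number difference would give, but rests on few reads. The median block gene stood at the 90.8th percentile of tested genes in the scrambled and at the 51st in the knockdown libraries. Regional silencing was not separated from copy number, DNA was not measured, and which line changed and whether inhibiting miR-27a had any part in it stay open.

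The small rise of chromosome 8 as a whole may, as a hypothesis, reflect a difference in chromosome dosage, for example in part of the cells. It was spread over the chromosome, with the lowest of 4 equal parts 0.173 above the genome-wide median on the log2 scale and the highest 0.215. GC content, transcript length and expression level are argued against as the cause, since after a fit on them the median was 0.198 (0.206 before, 630 of 649 genes). Release from miR-27 through 3′ UTR sites is argued against by the 332 genes without the core, at 0.207. DNA was not measured, and a change in the lines unrelated to the knockdown stays open, as it does for the smaller shifts of other chromosomes.

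The 0.0232 shift of genes with a miR-27 8mer site is in the direction that release from miR-27a would give, but shifts of this size arose without the site. It lay at the 80th percentile of 200 reordered 8mers of the same base composition (84.6th among the 149 without CpG), and 95 of the 200 also reached an exact p under 0.05. Almost all of the 200 lay in fewer genes than the 730 with the site, so this is not a percentile among like-sized sets. The median of the 200 was −0.00336, and they went both ways. The site's shift lay inside their middle 95% (−0.107 to 0.0616), so base composition was not excluded. What sets such groups of genes apart was not found. The block genes are argued against as the source of the site's shift, since without them it was 0.0196 (exact p = 0.0286), and it was 0.02777 without chromosome 8 as well. A weak effect of lost miR-27a activity stays open, because mature miR-27a was not measured and the lines differ in other ways.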
